A study of Homo sapiens with 6 samples.

How the data were processed

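Per the labels' protocols, total RNA of A549 lung cancer cells was collected from wild-type cells and from cells overexpressing HIF-1β, and the treatment field reads transfection without saying whether it was transient or stable. The cells were grown in RPMI medium with 10% fetal bovine serum, 1% L-glutamine and 1% antibiotics at 37 °C and 5% CO2. The labels conflict on the RNA: the molecule field names polyA RNA, whereas the protocol names a stranded total RNA kit with ribosomal RNA depletion. Each group had 3 libraries, numbered 1 to 3, and the batch field gives each library its replicate number. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No cell line authentication is given in the sources used here.

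The deposited table holds estimated counts per gene for 78932 Ensembl gene IDs; the name of the table credits them to salmon, a transcript quantifier. The submitters' processing notes name bcl2fastq 2.20 and the GRCh38 build. The salmon version, the annotation release, the library strand setting and the way transcripts were summed to genes are not given in the sources used here. The table holds 6 further columns of per-sample values, named for another lung cancer cell line, H460, which match no sample of the series and were not used here. Up to 9.51% of values in a library were not whole (further than 1e-06 from a whole number), and the expected counts as deposited were rounded to whole numbers before testing. A salmon estimate shares reads between similar transcripts, so genes with near-identical copies can exchange counts.

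Gene symbols came from a reference table that matched 61481 of the 78932 IDs (77.9%). Of the 16091 tested genes 14526 had a symbol. Gene positions came from GENCODE release 29 on GRCh38, 1-based, and 94.2% of tested genes had one. Genes were kept by the edgeR function filterByExpr at its smallest count of 10. Library totals were 17192161 to 24454236 counts, and TMM factors were 1.03 to 1.05 in the overexpression libraries and 0.948 to 0.977 in those labelled wild type. CPM values are counts divided by the TMM-scaled total of the tested genes. The test was the edgeR quasi-likelihood F test without a replicate term, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. The common biological coefficient of variation was 0.106. Folds in the text are ratios of group mean CPM, except where a group had 3 counts or fewer. Where a group had 0 reads, the fold is a lower bound set by 3 counts over that group. Where it had 1 to 3 counts, the fold compares counts summed over each group, divided by the summed TMM-scaled totals. Such a fold is given with a 95% counting interval.

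Before the data were examined, 23 gene lists were written, 8 of them on the subject of the study: bHLH-PAS factors and oxygen sensing, hypoxia response, glycolysis, AHR targets, the 3 sphingolipid lists, and mTOR complexes and AGC kinases. The named genes were also set by a rule fixed then. It takes ARNT; the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 1 CPM and group ranges that do not overlap; up to 6 called members of each list by smallest p; and up to 4 further members of the 8 subject lists by highest mean CPM. It gave 181 genes, of which 176 were called, and a part of the genes it gave is described; some others are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 23 lists. Repeats used an estimated correlation and fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes.

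No pair of libraries repeated each other. Over genes with enough counts in the pair compared, chi-square per degree of freedom was 5.66 to 14.6 within groups, above the 1 expected of sampling noise. The batch field gives the replicate numbers, so the numbers pair the libraries by the labels. Deviations from the group means correlated across genes by 0.0013, 0.096 and 0.022 between libraries of the same number and by -0.070 to 0.047 between libraries of different numbers. Among genes above the median of mean CPM these ranges were 0.088 to 0.21 and -0.14 to -0.0096, so pairs of the same number lay above all others. The first principal component of log2 CPM held 92.7% of the variance and separated the groups. Batch and group are crossed, with 1 library of each group per batch, so a fit with the batch as a block was possible.

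The steps were checked on simulated counts drawn from the means and library sizes of this comparison, with a seeded set of genes changed by known amounts. Over 15707 genes, edgeR recovered 53.1% of genes changed 1.5-fold, 70.8% of genes changed 2-fold and 87.9% of genes changed 4-fold, with 10 false calls among 15512 unchanged genes, which made 6.76% of its calls. The share of false calls was 9.40% with the replicate block and 10.8% with DESeq2, above the 5% aimed at. Few genes were changed in the simulation, whereas 74.0% of tested genes were called here, so the adjusted threshold was stricter there. The shares recovered and falsely called therefore do not carry over to the real comparison. Alternatives fixed beforehand were DESeq2 size factors, library totals alone, no filter on low counts, a filter of 1 CPM in at least 3 libraries, the DESeq2 Wald test, limma-voom, robust quasi-likelihood, a replicate block and leaving out each library. Thinning to the smallest library was added after seeing the main results and before its own result was seen. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.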

Results

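Gene-level transcript abundance was measured by RNA sequencing in 6 libraries labelled as A549, an established human lung adenocarcinoma cell line: 3 libraries labelled wild type and 3 libraries labelled as overexpressing HIF-1β after transfection. HIF-1β, encoded by ARNT, is the partner with which HIF-1α, HIF-2α and the aryl hydrocarbon receptor bind DNA. The series title ties HIF-1β to the mTORC2 kinase complex and to sphingolipid metabolism, so the single comparison asks which transcripts, sphingolipid genes among them, differ when HIF-1β is raised. The libraries held 17192161 to 24454236 counts, and 16091 of 78932 listed genes had enough counts to be tested. Levels are given as CPM (counts scaled to the TMM-adjusted total of the tested genes, mean ± SD, n = 3), with the overexpression libraries first. At this depth 3 counts summed over a group corresponded to 0.0439 CPM in the overexpression group and 0.0501 CPM in the wild-type group, and these floors cover counting error only.

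ARNT was higher in the overexpression libraries, at 139 ± 8.30 against 43.7 ± 5.67 CPM, which is 3.18-fold (log2 fold change 1.67, SE 0.095, adjusted p = 6.5e-08). The lowest overexpression library, at 130.0 CPM, lay above the highest wild-type library, at 50.04 CPM. The direction therefore matched the group labels. ARNT (ENSG00000143437) lies on chromosome 1, 150809705 to 150876768, minus strand, in GRCh38, and counts over the whole gene do not separate introduced from endogenous transcripts. The 40 nearest tested genes had a median log2 fold change of -0.17. In all, 3931 tested genes, 24.4%, differed by at least as much as ARNT.

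Across the transcriptome, 11908 of the 16091 tested genes (74.0%) differed between the groups, 6158 of them higher and 5750 lower in the overexpression libraries. Of these, 6056 differed by more than 2-fold, 3727 higher and 2329 lower. With TMM scaling the median log2 fold change of all tested genes was 0.034. With library totals as the only scaling, 6817 genes were higher and 4993 lower, so the balance of directions depends on the scaling. The CPM ranges of the groups did not overlap for 12436 tested genes (77.3%), where chance would give 10%. Libraries of a group resembled each other, with a Pearson correlation of log2 CPM across genes of 0.985 to 0.988, against 0.757 to 0.776 between groups. Genes are not independent replicates, so these correlations describe the libraries only. The median log2 fold changes of 20 of 143 runs of 100 neighbouring genes lay outside the range reached when gene order was shuffled 100 times, 13 of them above it and 7 below it. The highest run, on chromosome 19 from 38899700 to 43852017, had a median log2 fold change of 1.24, with 91% of its genes higher.

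**Figure D1:**
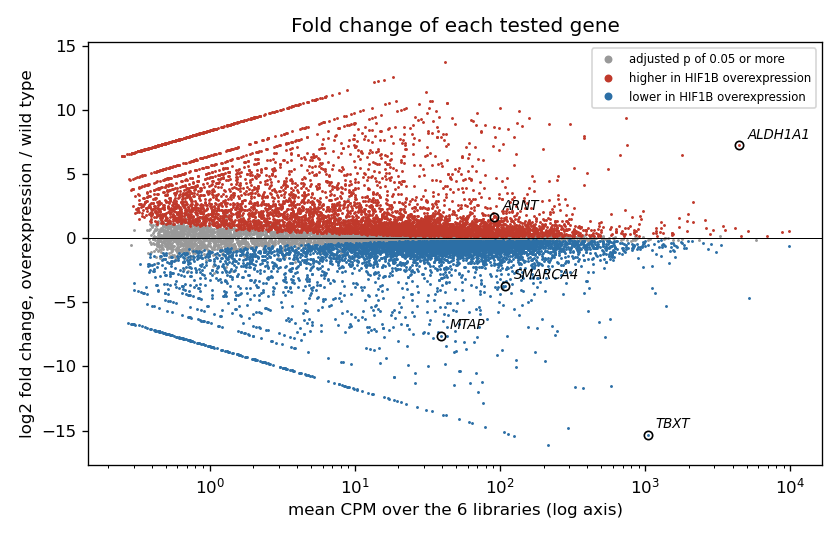
Log2 fold change (overexpression over wild type) of each of the 16091 tested genes against its mean CPM over the 6 libraries, on a log axis; red and blue points are the 6158 genes higher and 5750 genes lower at an adjusted p under 0.05, and grey points are the rest. Points far from 0 lie on both sides at all levels; the slanted lines at low CPM are genes with few or no reads in a group, whose fitted fold change depends on the prior count.

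Many genes were present in only a single group. At 10 CPM or more in every library of a group and 0 reads in all libraries of the other, 14 genes were detected in the overexpression libraries alone and 37 in the libraries labelled wild type alone. Among the largest rises were PRICKLE2, XAGE1A, ANXA8L1, BMPR1B, ADAMTS12, CDKN2B-AS1, TGFB1I1, MID2 and NR5A2. PRICKLE2, at 36.6 ± 4.26 CPM, was at least 731-fold higher, and BMPR1B, a bone morphogenetic protein receptor at 29.1 ± 4.0 CPM, at least 579-fold higher. XAGE1A and ANXA8L1 have near-identical copies, so their counts are uncertain. The largest falls were in TBXT, GJA5, LINC00824, PAG1, CDH13, EPB41L3, GPR65, MEF2C, HOPX and ENG. TBXT (chromosome 6, 166157656 to 166168700), which encodes the mesoderm factor brachyury, fell from 2076 ± 294 CPM in the libraries labelled wild type to 3 reads in the overexpression libraries, 47007-fold (counting interval 16085 to 227943). GJA5, which encodes the gap junction protein connexin 40, was at 428 ± 30.9 CPM in the libraries labelled wild type and had no reads in the overexpression libraries, at least 9682-fold lower. MEF2C, a transcription factor of muscle and other mesoderm, was at least 2786-fold lower.

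The region around CDKN2A on chromosome 9 was read out differently in the groups; CDKN2B-AS1 was named by the rule fixed beforehand, and the other genes of this paragraph were chosen after their values were seen. A549 is known to have lost CDKN2A and the adjoining MTAP, which encodes an enzyme of methionine salvage. MTAP (chromosome 9, 21802543 to 21937651) was at 0.400 ± 0.234 CPM in the overexpression libraries and at 78.1 ± 5.01 CPM in the libraries labelled wild type, a 195-fold difference (adjusted p = 1.5e-10). CDKN2A (chromosome 9, 21967753 to 21995301) and CDKN2B (chromosome 9, 22002903 to 22009363) had 0 reads in all 6 libraries. CDKN2B-AS1 (chromosome 9, 21994778 to 22121097) was at 12.8 ± 0.799 CPM in the overexpression libraries and had 0 reads in the libraries labelled wild type, at least 255-fold higher. DMRTA1 (chromosome 9, 22446841 to 22455740) was at 1.27 ± 0.296 CPM and 0 reads. Counts of CDKN2B-AS1, which overlaps CDKN2A and CDKN2B on the opposite strand, are uncertain because the strand setting of the counting is not given in the sources used here. Elsewhere, SMARCA4, a chromatin remodelling ATPase that A549 is known to carry in mutated form, was 12.9-fold lower in the overexpression libraries, at 15.6 ± 1.83 against 201 ± 4.33 CPM. GSTM1, a glutathione transferase that many people lack, had 2 reads in the overexpression libraries and 96.0 ± 4.19 CPM in those labelled wild type. ALDH1A1 was at 8835 ± 741 against 57.4 ± 14.6 CPM, the vitamin D hydroxylase gene CYP24A1 at 1463 ± 357 against 2.27 ± 1.52 CPM and the epithelial keratin gene KRT7 at 1481 ± 94.6 against 9.45 ± 3.79 CPM. These differences separated the same libraries as each gene group described from here on.

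**Figure D2:**
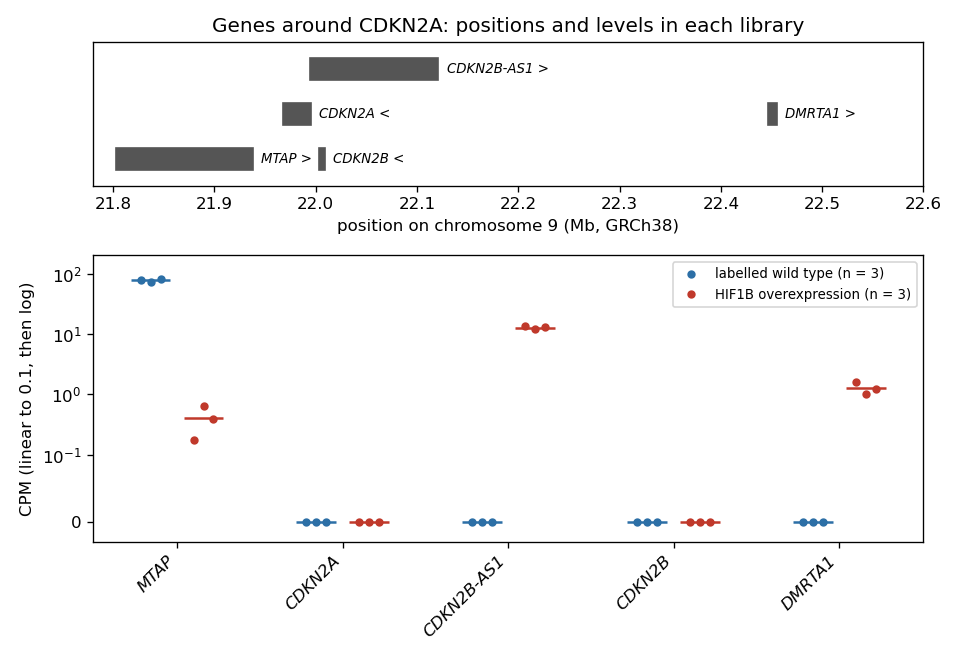
Position of 5 genes on chromosome 9 in Mb (GRCh38; arrowheads give the strand) and their CPM in each library, on an axis that is linear up to 0.1 CPM and logarithmic above; points are libraries and bars are group means (n = 3). MTAP was at 78.1 CPM in the libraries labelled wild type and 0.400 CPM in the overexpression libraries, CDKN2B-AS1 and DMRTA1 were detected only in the overexpression libraries of these 6, and CDKN2A and CDKN2B had 0 reads in each.

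Among bHLH-PAS factors and oxygen-sensing genes, 13 of 19 tested members were higher in the overexpression libraries, 5 were lower and 1 did not pass the test. ARNT2, the paralog of ARNT, differed most, at 55.0 ± 0.906 against 1.03 ± 0.135 CPM (53.4-fold higher, log2 fold change 5.72, SE 0.12). EPAS1, which encodes HIF-2α, was 2.53-fold higher at 383 ± 20.1 against 151 ± 7.41 CPM, and HIF1A was 1.60-fold higher at 457 ± 38.4 against 286 ± 11.8 CPM. The clock gene BMAL2 was 6.38-fold higher, and the oxygen-sensing prolyl hydroxylase gene EGLN1 1.41-fold higher. AHR, the aryl hydrocarbon receptor, was 3.50-fold lower at 50.6 ± 5.00 against 177 ± 8.76 CPM, and CLOCK was 2.03-fold lower. The coactivator genes CREBBP and EP300 differed least among the named members, at 1.27-fold and 1.21-fold lower; with library totals as the only scaling EP300 no longer passed (adjusted p = 0.097). Against all other genes the list as a whole was not called (camera, adjusted p = 0.18).

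**Figure D3:**
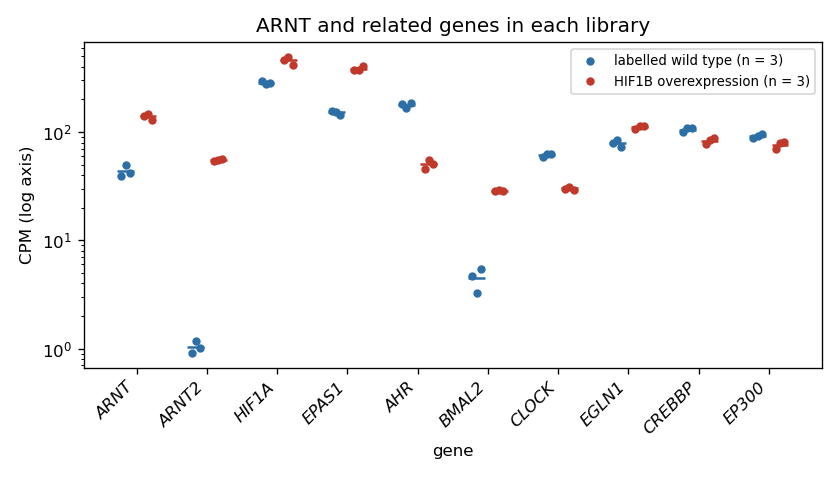
CPM (log axis) of ARNT and 9 further genes of the bHLH-PAS and oxygen-sensing list in each library; points are libraries and bars are group means (n = 3 per group). ARNT, ARNT2, HIF1A, EPAS1, BMAL2 and EGLN1 were higher and AHR, CLOCK, CREBBP and EP300 lower in the overexpression libraries.

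Hypoxia response genes went both ways, with 16 of 38 higher, 16 lower and 6 not passing. CA12, a membrane carbonic anhydrase, was 92.8-fold higher at 1321 ± 195 against 14.2 ± 3.02 CPM, and the glycolytic regulator PFKFB3 was 10.4-fold higher at 456 ± 65.8 against 44.1 ± 2.02 CPM. The collagen-modifying enzyme gene PLOD2 was 4.51-fold higher. VEGFA, the angiogenic growth factor, was instead 3.42-fold lower at 48.3 ± 4.95 against 165 ± 11.5 CPM, PDK1, a kinase that restrains pyruvate dehydrogenase, 4.39-fold lower, and the mTORC1 inhibitor DDIT4 2.47-fold lower. LOXL2 was 1.36-fold lower, and MIF, which did not pass, was at 300.3 ± 3.64 against 293 ± 23.9 CPM. The list was not called (adjusted p = 0.78); its median log2 fold change was -0.0056, its mean 0.26 and its camera direction up, and with DESeq2 size factors or library totals the median was above 0.

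Glycolysis genes were more often lower, with 12 of 22 lower, 7 higher and 3 not passing. Hexokinase 2, encoded by HK2, was 41.0-fold lower at 1.84 ± 0.209 against 75.5 ± 6.78 CPM, and HK1 was 2.6-fold lower. PFKM, a phosphofructokinase gene, was 2.40-fold lower and SLC16A1, a lactate transporter gene, 1.77-fold lower. ENO2 was 9.83-fold higher and PKM, at 3320.0 ± 156 against 1931 ± 202 CPM, 1.72-fold higher, whereas ENO1 was 1.44-fold lower. LDHA was 1.13-fold lower (adjusted p = 0.031), a call lost with DESeq2 size factors (adjusted p = 0.052), with library totals (0.39), with the filter at 1 CPM (0.051) and without overexpression replicate 1 (0.074), overexpression replicate 2 (0.074), wild-type replicate 1 (0.064) or wild-type replicate 2 (0.054). GAPDH did not pass, at 5573 ± 267 against 6033 ± 281 CPM; it passed with a replicate block (adjusted p = 0.036) and without wild-type replicate 2 (0.038). The list was not called (adjusted p = 0.18).

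Of 15 tested AHR target genes, 8 were lower, 5 higher and 2 did not pass. SERPINB2 had no reads in the overexpression libraries and was at least 330.5-fold lower. The drug transporter gene ABCG2 was 2.53-fold lower, the antioxidant regulator NFE2L2 2.01-fold lower, NQO1 1.64-fold lower at 1439.8 ± 51.8 against 2367 ± 21.3 CPM, and CYP1B1, a xenobiotic-metabolising cytochrome, 1.64-fold lower. The amino acid transporter gene SLC7A5 was 2.07-fold higher and LRP5 1.75-fold higher. TIPARP was 1.39-fold higher and ALDH3A1 1.39-fold lower; the first call was lost without overexpression replicate 3 (adjusted p = 0.051) and the second without wild-type replicate 1 (0.053). As a list they were not called (adjusted p = 0.34).

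Sphingolipid genes were covered by 3 lists, compared between the same libraries in which MTAP was at 0.400 and 78.1 CPM. In de novo synthesis, which runs from serine and palmitoyl-CoA to ceramide, 8 of 18 tested genes were higher, 8 lower and 2 did not pass. SPTLC3, a subunit of serine palmitoyltransferase, was 21.1-fold lower at 0.767 ± 0.384 against 16.2 ± 1.45 CPM, and the ceramide synthase gene CERS6 was 2.82-fold lower at 81.4 ± 4.12 against 229.6 ± 13.6 CPM. Of the ORMDL regulators of serine palmitoyltransferase, ORMDL1 was 2.07-fold lower and ORMDL3 2.35-fold higher. SPTSSA, a small subunit of the same enzyme, was 1.69-fold higher, HACD3 1.45-fold higher and TECR 1.26-fold higher. RTN4 was 1.51-fold lower, CERS2, the most abundant ceramide synthase transcript of the list at 228 ± 12.5 against 287 ± 18.1 CPM, 1.26-fold lower, and the dihydroceramide desaturase gene DEGS1 1.21-fold lower, a call lost with library totals (adjusted p = 0.11). The synthesis list was not called (adjusted p = 0.78), and its median log2 fold change of -0.030 was above 0 with library totals.

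Genes of ceramide breakdown and sphingosine 1-phosphate were mostly higher, with 13 of 16 higher, 2 lower and 1 not passing. The receptor genes S1PR3 and S1PR5 were 7.90-fold and 23.6-fold higher, at 72.8 ± 12.1 against 9.21 ± 1.73 CPM and 5.05 ± 0.748 against 0.214 ± 0.178 CPM. The lipid phosphatase gene PLPP3 was 5.41-fold higher, PLPP1 1.96-fold higher and PLPP2 1.20-fold higher. SGPP2, a sphingosine 1-phosphate phosphatase gene, was at 3.52 ± 1.08 CPM against 2 reads in the libraries labelled wild type, 105-fold (counting interval 29 to 865). Acid ceramidase, encoded by ASAH1, was 1.45-fold higher at 89.1 ± 2.73 against 61.4 ± 3.83 CPM, and ALDH3A2, which acts at the end of the pathway, 1.5-fold higher. Neutral ceramidase, encoded by ASAH2, was 5.44-fold lower, and the lyase gene SGPL1, which did not pass, was at 109 ± 2.01 against 116 ± 4.09 CPM. Against other genes the list was not called (camera, unadjusted p = 0.031, adjusted p = 0.18, and adjusted p = 0.92 with an estimated correlation).

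Among genes of complex sphingolipid synthesis and turnover, 14 of 37 were higher, 13 lower and 10 did not pass. FA2H, which hydroxylates the fatty acids of sphingolipids, was 128-fold higher at 43.8 ± 9.43 against 0.342 ± 0.141 CPM, and the sulfatide synthase gene GAL3ST1 189-fold higher. The galactosylceramidase gene GALC was 19.3-fold lower at 37.6 ± 5.61 against 724 ± 135 CPM. UGCG, which makes glucosylceramide, and SGMS1, which makes sphingomyelin, were 2.82-fold and 2.56-fold lower. The hexosaminidase gene HEXA was 2.25-fold higher and the α-galactosidase gene GLA 2.15-fold lower. PSAP, the saposin precursor gene, and SMPD4 did not pass, at 862 ± 76.9 against 874 ± 53.8 CPM and 118 ± 11.5 against 121 ± 5.73 CPM. This list was not called (adjusted p = 0.80); its median log2 fold change was -0.014, its mean 0.59 and its camera direction up, and its median was above 0 with DESeq2 size factors and with library totals.

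**Figure D4:**
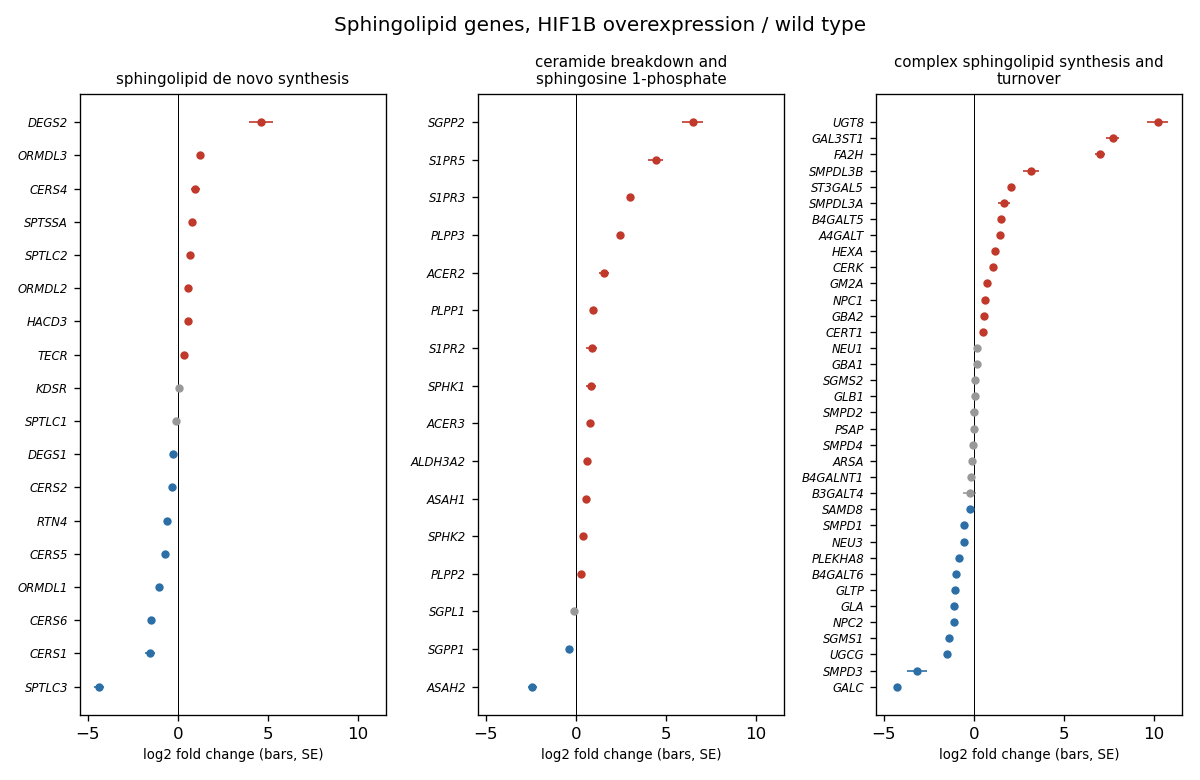
Log2 fold change (overexpression over wild type, with SE) of the tested members of the 3 sphingolipid lists, not all of which are drawn; red genes were higher and blue genes lower at an adjusted p under 0.05, and grey genes did not pass. Higher genes numbered 8 of 18, 13 of 16 and 14 of 37, and the fitted value of a gene with 0 reads in a group depends on the prior count.

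Genes of the mTOR complexes and AGC kinases also split, with 12 of 25 higher, 8 lower and 5 not passing. PRR5L, a component of mTORC2, was 49.4-fold lower at 2.91 ± 0.415 against 144 ± 2.16 CPM. The kinase gene SGK1, an mTORC2 substrate, was 3.32-fold lower, while SGK2 was at 14.8 ± 1.13 CPM against 3 reads, 294-fold (counting interval 101 to 1428). AKT2 was 2.61-fold higher at 215 ± 7.68 against 82.1 ± 3.31 CPM, AKT1 1.47-fold lower at 182 ± 10.8 against 268 ± 15.0 CPM and PRKCA 2.04-fold higher. MTOR itself was 1.42-fold lower and RHEB 1.64-fold lower. MAPKAP1, which encodes the mTORC2 subunit SIN1, was 1.19-fold higher, a call lost without wild-type replicate 3 (adjusted p = 0.059). These genes too were compared between libraries that differed in MTAP and TBXT. The list was not called (adjusted p = 0.78), its median log2 fold change of 0.25 and mean of 0.20 lying above 0 while its camera direction was down.

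Of 23 lists, 2 differed from other genes, and both calls were lost with an estimated correlation. Genes of the unfolded protein and integrated stress response were lower, with 24 of 30 lower, 3 higher and 3 not passing (camera, adjusted p = 6.4e-08; adjusted p = 0.72 with an estimated correlation). The pseudokinase gene TRIB3 was 9.88-fold lower at 72.9 ± 9.78 against 721 ± 12.8 CPM, and DDIT3, which encodes the stress transcription factor CHOP, 15.1-fold lower at 6.12 ± 1.58 against 92.6 ± 9.56 CPM. HERPUD1, which acts in degradation at the endoplasmic reticulum, was 6.10-fold lower, and asparagine synthetase, encoded by ASNS, 4.57-fold lower. SHMT2, a mitochondrial enzyme of serine metabolism, was 6.07-fold lower. NF-κB and inflammatory cytokine genes were also lower, with 15 of 23 lower, 6 higher and 2 not passing (adjusted p = 0.033; adjusted p = 0.72 with an estimated correlation). CXCL8, which encodes interleukin 8, was at 0.394 ± 0.0323 against 1169 ± 649.9 CPM, and the NF-κB inhibitor TNFAIP3 was 52.6-fold lower at 3.62 ± 0.310 against 190.4 ± 18.8 CPM. The chemokine genes CXCL1 and CXCL2 were 36.1-fold and 13.9-fold lower. IL11 and PTGS2, a prostaglandin synthase gene, were instead 92.3-fold and 21.9-fold higher. Both lists were compared between the libraries that also differed in MTAP, at 0.400 and 78.1 CPM. The NF-κB list was no longer called with the filter at 1 CPM (adjusted p = 0.059) or without overexpression replicate 3 (adjusted p = 0.051).

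Interferon response genes showed 14 of 33 higher, 11 lower and 8 not passing, and 15 higher and 11 lower when adjusted over the list alone; for the other 22 lists the count adjusted over the list alone equalled the count over all genes tested. IFI44L was at 32.5 ± 2.95 CPM in the libraries labelled wild type against 3 reads, 739-fold (counting interval 253 to 3581), and IFIT2 and OAS1 were 14.2-fold and 3.41-fold lower, whereas HERC5 was 59.5-fold higher. The list was not called (adjusted p = 0.78), with a median log2 fold change of 0.014, a mean of -0.22 and a camera direction of down.

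Markers of epithelial and mesenchymal state were not called as a list (camera, adjusted p = 0.78), with 18 of 29 higher, 10 lower and 1 not passing. The list joins markers of both states, so a shift between them could cancel in a test of a single direction. CDH1, the epithelial adhesion molecule E-cadherin, was at 228 ± 25 against 0.672 ± 0.793 CPM, 339-fold higher, and KRT8 was 2.66-fold higher. Another epithelial marker, KRT19, was 418-fold lower at 0.497 ± 0.132 against 208 ± 17.1 CPM. The mesenchymal factor ZEB2 was 13.4-fold lower and fibronectin, FN1, 25.1-fold lower at 399 ± 87.8 against 10032 ± 1039 CPM. Of 29 extracellular matrix and adhesion genes, 15 were higher, 12 lower and 2 did not pass (adjusted p = 0.85). The collagen gene COL12A1 was 51.9-fold lower, while the basement membrane collagens COL4A1 and COL4A2 were 8.32-fold and 8.41-fold higher and the integrin gene ITGB4 118-fold higher.

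Alveolar and airway epithelial markers included 8 higher, 3 lower and 2 not passing of 13 tested (adjusted p = 0.21). With a replicate block the list was called (adjusted p = 0.032), as it was without overexpression replicate 2 (adjusted p = 0.035), and with an estimated correlation it was not (adjusted p = 0.72). The mucin gene MUC5B was 642-fold higher at 315 ± 89.2 against 0.491 ± 0.260 CPM, the endoderm factor FOXA2 576-fold higher at 54.7 ± 1.90 against 0.0949 ± 0.130 CPM and the lamellar body lipid transporter gene ABCA3 5.16-fold higher. FOXA1 was 4.77-fold lower, and HOPX, at 105 ± 11.5 CPM in the libraries labelled wild type, had no reads in the overexpression libraries and was at least 2377-fold lower. Markers of fibroblasts, endothelium and blood cells were scarce, with 5 of 23 tested; 2 were higher, 2 lower and 1 did not pass (adjusted p = 0.85). Among them COL3A1 was at 13.0 ± 2.62 CPM in the libraries labelled wild type against a single read, and COL1A1 and CD14 were 9.83-fold and 13.9-fold higher in the overexpression libraries.

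Cholesterol and fatty acid synthesis genes were mostly higher, with 17 of 27 higher, 6 lower and 4 not passing, but the list was not called (adjusted p = 0.18). ATP citrate lyase, encoded by ACLY, was 4.73-fold higher at 1205 ± 18.8 against 255 ± 20.9 CPM, the desaturase gene FADS2 5.21-fold higher, and the sterol synthesis genes SQLE and HMGCS1 3.15-fold and 2.91-fold higher. The sterol carrier gene STARD4 was 13.5-fold lower. Of 27 NRF2 targets, 13 were higher, 12 lower and 2 did not pass (adjusted p = 0.80). HMOX1, heme oxygenase 1, was 11.4-fold higher, and SRXN1, sulfiredoxin, 4.46-fold lower; AKR1C2, 7.11-fold higher, shares sequence with its close paralogs and is uncertain. Cell cycle genes had 16 of 34 higher, 6 lower and 12 not passing (adjusted p = 0.61), with TOP2A 3.12-fold higher, cyclin E1 (CCNE1) 6.28-fold higher and RRM2 2.47-fold lower. Of 26 p53 targets, 9 were higher, 13 lower and 4 did not pass (adjusted p = 0.55). The stress cytokine gene GDF15 was 8.56-fold lower and MDM2, which restrains p53, 2.13-fold lower, while BAX was 2.49-fold higher. Apoptosis and autophagy genes split into 12 of 32 higher, 14 lower and 6 not passing (adjusted p = 0.65). The survival gene BCL2 was 16.3-fold lower and BCL2L1 3.01-fold higher.

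Mitochondrially encoded transcripts were higher, with 12 of 13 higher, 0 lower and 1 not passing, though the list was not called (adjusted p = 0.21). MT-CO3 was 1.80-fold higher at 5302 ± 294 against 2953 ± 9.21 CPM and MT-ATP6 1.60-fold higher. Mitochondrial transcripts took 5.11% to 5.69% of the counts in the overexpression libraries and 3.47% to 3.59% in those labelled wild type. Nuclear genes of oxidative phosphorylation were more often lower, with 17 of 32 lower, 7 higher and 8 not passing (adjusted p = 0.49). The ATP synthase gene ATP5F1B was 2.03-fold lower at 975 ± 18.8 against 1981 ± 20.5 CPM, the complex I gene NDUFS1 2.13-fold lower, and the complex III gene UQCRFS1 2.45-fold higher. Replication-dependent histone genes, many of them near-identical and at low levels, had 3 of 16 higher, 7 lower and 6 not passing (camera, adjusted p = 0.80). H2AC6 was 2.09-fold higher and H1-4 4.21-fold lower. Scaling by library totals moved the median log2 fold change of all tested genes up by 0.11, and the calls of EP300, DEGS1 and LDHA were lost with it.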

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

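Over the 15 alternatives 10986 to 13591 genes were called, calls shared with the reported ones had the reported direction, and ARNT stayed higher and past the threshold. DESeq2 called 12325 of 21460 tested genes and limma-voom 12006 of 16091. Without the filter on low counts 13591 of 30282 tested genes were called, so the share of 74.0% in the main fit depends on which genes are tested. With a replicate block, where libraries of a batch are paired, 11960 were called, and no count of genes moved by more than 1.5 times. Leaving out each library in turn gave 11356 to 11895 changed genes, 6177 to 6376 changed more than 2-fold, a log2 fold change of ARNT of 1.58 to 1.77, and 174 to 175 of the 176 called named genes. Thinning to the smallest library, the only alternative chosen after seeing the data, though before its own result was seen, called 11536 genes and left ARNT at 1.65. Single named genes lost a call 12 times and gained it 2 times over all alternatives, and none changed direction while called; LDHA accounted for most losses.

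The gene lists were less stable. Of the 2 lists called with a preset correlation, 0 were called with an estimated correlation, where the smallest unadjusted p was 0.051; fry, which does not compare a list with other genes, called 17. The filter at 1 CPM left 1 list, and leaving out a library gave 1 to 3. The replicate block added the alveolar and airway list (adjusted p = 0.032), for 3 lists, and GAPDH (adjusted p = 0.036), and it changed no other call of a list or named gene. The mean correlation of same-numbered libraries was 0.040 over all tested genes and 0.14 over genes above the median of mean CPM; the cause was not tested. Library totals raised the share of higher calls from 51.7% to 57.7%. In the simulation, where few genes changed, 53.1% of changes of 1.5-fold were recovered. With 74.0% of tested genes called here the adjusted threshold was less strict, so that share does not carry over. Smaller changes can still be missed, but how often was not tested. Since the doubt about the identity of the cells concerns each library labelled wild type, no count could be repeated without the doubted libraries.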

Other observations

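All tests on the region around CDKN2A, the test for added RNA of other cells and the comparison of ARNT with its family were chosen after the results they measure were seen; the tests on runs of neighbouring genes, on library depth (thinning) and on the neighbours of ARNT were added after the main results but before their own were seen.

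The genes of this paragraph belong to none of the lists and were chosen after their values were seen, so they stand for no cell type or pathway. The transcription factor HNF4A was at 73.0 ± 11.1 against 0.333 ± 0.293 CPM. The fibrinogen genes FGA, FGB and FGG, which make a plasma clotting protein, were at 43.4 ± 3.16, 50.3 ± 11.1 and 16.9 ± 3.96 CPM in the overexpression libraries and at 0.106, 0.314 and 1.39 CPM in those labelled wild type. The surface glycoprotein gene CEACAM6 was at 52.0 ± 4.68 against 0.0746 ± 0.0653 CPM. The growth regulators HMGA2 and LIN28B were 208-fold and 38.5-fold higher, at 19.7 ± 3.44 against 0.0948 ± 0.0913 CPM and 12.1 ± 1.43 against 0.314 ± 0.108 CPM. In the other direction, the matrix genes EFEMP1 and LAMA1 were at 5.09 ± 0.239 against 1047 ± 57.1 CPM and 0.219 ± 0.0712 against 749 ± 56.8 CPM. SMARCA2, the paralog of SMARCA4, did not pass, at 65.2 ± 6.47 against 55.4 ± 8.87 CPM (adjusted p = 0.091).

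The first pattern is that MTAP and CDKN2B-AS1, beside CDKN2A, were each above 10 CPM in a single group. MTAP, which A549 is known to lack, averaged 78.1 CPM in the libraries labelled wild type, which is consistent with these coming from cells other than A549; at 0.400 CPM in the overexpression libraries it does not single out A549, since other lines can lack it, so whether those come from another line cannot be told apart. Weak expression of the whole region at this depth does not account for 2 genes, MTAP and CDKN2B-AS1. Each was above 10 CPM in every library of a group and at most 1 CPM in every library of the other. These bounds were set after the values were seen, and the counts of CDKN2B-AS1 are uncertain because the strand setting is not given. Other rows go the other way or with neither: CDKN2A had 0 reads in both groups, CDKN2B-AS1, which overlaps it, had 873 reads in the overexpression libraries and 0 in the others, and MTAP still had 27 in the former; RNA levels do not show DNA, so loss and silencing of these genes both stay open. Which line the libraries labelled wild type hold, and whether the label, the sample or the column name went wrong, was not tested; the table's 6 columns named for H460 would bear on it but match no sample of the series and were not used here.

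The second pattern is that 74.0% of tested genes differed. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 11908 genes, the highest other split 0 and 1 split, the real one, as many. Every other split mixes libraries of both groups on each side, which adds the difference between the groups to its spread. Its 0 calls are therefore no evidence about the real split. Medians of runs of 100 neighbouring genes had an SD of 0.348, against at most 0.138 in 100 shuffles of gene order. Of these runs, 20 lay outside all shuffled ones. Copy number that differs between the cells of the groups would give such runs. They argue against HIF-1β acting in cells of a single genome as the whole cause. This assumes that a transcription factor does not move whole stretches of a chromosome. Shuffling also breaks up neighbouring genes that are regulated together, and no comparison within a single genome was run to gauge that effect. A mixture of A549 with other cells in the libraries labelled wild type cannot be told apart from the rest: 309 genes above 10 CPM in the overexpression libraries lay under 5% of that level in the others (upper 95% limit), but HIF-1β could have induced such genes, and no further library of unmodified A549 was analysed here. Thinning each library to the smallest total left 11536 genes called, which argues against library depth, and how much of the difference HIF-1β itself accounts for was not tested and stays open.

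The third pattern is the higher ARNT in the overexpression libraries. The 40 nearest tested genes had a median log2 fold change of -0.17 (bootstrap interval -0.33 to 0.13), below the bound of 0.83 set as 50% of the change of ARNT, which argues against a gain of the region as the whole cause. A difference between the cells other than the introduced gene stays open and cannot be told apart from the overexpression, since 3 of 18 tested family members, ARNT2, AHR and BMAL2, none of which the labels name as introduced, differed by at least as much. A hypothesis left by these values is that the comparison joins HIF-1β overexpression with a change of cell line. The gene lists, sphingolipid genes included, may reflect either, and genotypes of the 6 libraries would test for a change of line. The labels name no empty-vector or mock-transfected library, so an effect of transfection itself cannot be told apart from that of HIF-1β.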
